A study of Arabidopsis thaliana with 12 samples.

How the data were processed

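Gene expression was measured in sorted green fluorescent cells of Arabidopsis root tips on 12 single-colour Affymetrix ATH1 arrays, 3 from each of 4 lines, at 5 days. The deposited value table holds 1 intensity per probe set and array on a linear scale. Per the submitters' processing notes, the values were made with MAS5; its version, the background correction and any scaling are not given in the sources used here. The deposited intensity values ran from 0.513 to 44.2 with 66.1% of them under 1. The medians were 0.866, 0.858 and 0.855 on the control arrays, 0.794, 0.817 and 0.816 on the BLJ arrays, 0.785, 0.825 and 0.804 on the JKD arrays and 0.816, 0.861 and 0.812 on the SCR arrays, in replicate order. The scale of these values and whether they were centred stay unknown. The labels' protocols name both a labelling protocol with a single amplification round and one with an added round, without saying which array had which, so the protocol could not be used as a block.

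Groups and replicate numbers were taken from the titles of the arrays, and 0 columns of the table were left unused. The design, the alternatives and the fixed gene lists were written before the data were examined. The fixed rule took the table as normalized only if the 5% trimmed means of the arrays lay within 5% of their mean. JKD 1 deviated by 5.25%, so quantile normalization between arrays was used. The normalized values were taken to log2(value + 0.703), the offset being the 20th percentile of all values. Fold changes are on that scale, which understates the changes of dim probe sets. The 55 control probe sets were left out, as were the 30% of probe sets with the lowest mean over all arrays, and 15923 of 22746 were tested.

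The test was limma 3.58.1 in R 4.3.3, with a mean for each of the 4 groups over all 12 arrays, empirical Bayes moderation with trend and robust options and Benjamini-Hochberg adjustment. A probe set was called changed at an adjusted p under 0.05. Every adjusted p of a single gene is from this test. Means ± SD are over the 3 arrays of a group, on the quantile-normalized linear scale. The hybridization controls were tested in the same way in a fit that included the control probe sets and no filter. The replicates are labelled as biological replicates; with 3 arrays per group, their number limits the precision, and the values give no read depth.

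Gene names came from an annotation table of the platform, updated by gene number through a RefSeq table of assembly TAIR10.1, which was used for names only. Of the probe sets kept, 13513 have 1 gene, of which 13436 matched the RefSeq table, 503 have several genes and are not named, and 8730 are unnamed here. Where a locus had more than 1 probe set, which held for 144 loci, its brightest probe set stood for it in the gene lists. Many members of the fixed lists are among the unnamed probe sets.

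Named genes followed a fixed rule. It takes BLJ, JKD and SCR on every array, and the measured members of the network list. For each line against the control it takes the 10 highest and 10 lowest fold changes among called probe sets with 1 gene, a mean above the median probe set and every array of the line beyond every control array. For each fixed list it takes up to 2 called members per direction with the smallest p, or, with none called, up to 2 members as values. For line against line it takes the 5 highest and 5 lowest under the same conditions. Members of lists written later, the genes called in all 3 lines and the control probe sets were chosen outside this rule, the last 2 after their values were seen.

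Of 23 fixed lists, 5 had at least 3 members after the filter and were tested with camera at a preset correlation of 0.01, adjusted over 15 tests. A further 21 lists were put together from the gene names after the annotation had been read and before any comparison was run; these gave 60 tests adjusted on their own. Both sets were also tested with an estimated correlation and with fry. 2 lists, the class III peroxidases and heat shock genes, were chosen after values were seen. The peroxidase counts were tested with Fisher's exact test, one-sided, against the other tested genes, and again without the leading genes named for their fold change.

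Overlaps between lines were set beside independent lists and beside 100 simulated sets of unchanged groups against the same controls. The called members of each gene list were counted again with each array left out, a count added after the results were seen. For the probe sets lower in both the BLJ and JKD lines, an SCR line at the control means was simulated 50 times with the other lines unchanged and 50 times with them at their fitted effects. The ratio was taken over the 209 probe sets with the lowest t in both lines in the first case, and over those called lower in both in the second. The fit was tested on simulated data in which 200 probe sets were changed by 0.25, 0.5 or 1 on the log2 scale. It recovered 62.7%, 88.1% and 98.5% of them in the BLJ comparison with 3 false calls, 70.1%, 86.6% and 97.0% in the JKD comparison with 7, and 67.2%, 91.0% and 98.5% in the SCR comparison with 11. The simulated noise was independent between probe sets and held no differences between whole arrays. These rates therefore do not cover the dependence on single arrays.

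Other settings fixed in advance were intensities under 1 set to 1 with no offset, an offset at the 40th percentile (0.781), no filter or a 50% filter, the deposited scale, median centring, moderation without trend and robust options, array weights, only the 6 arrays compared, the replicate number as a fixed or random block, a 1.5-fold minimum, an adjusted p under 0.01, a covariate of RNA quality and each array left out in turn. The RNA quality covariate was the log2 ratio of 3' over 5' control probe sets. Plain log2 without an offset, a covariate of the heat shock genes and a fit without control 3, BLJ 1 and BLJ 3 were added after the data were seen. Permutation tests were exact and two-sided.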

Results

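Gene expression was measured on 12 single-colour ATH1 arrays of Arabidopsis root tip cells sorted for green fluorescence. J0571 is an enhancer trap line of ecotype C24 in which GAL4 and GFP mark the ground tissue, the cortex and endodermis of the root. The control group was J0571 alone, and the other groups were J0571 plants in which GAL4 drove a UAS copy of BLJ, JKD or SCR, transcription factors of ground tissue patterning. Each of the 4 groups had 3 independent replicates from seedlings of 5 days. The comparisons ask which genes change in ground tissue cells when each factor is driven there, and how the 3 lines differ from one another. The table held 22801 probe sets, and 15923 were tested. Arrays have no read depth, so the number of arrays limits the precision.

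The arrays correlated with one another at Pearson's r between 0.951 and 0.994 across probe sets, which are not independent replicates, and no columns were identical. Array medians lay between 0.785 (JKD 1) and 0.866 (control 1). The deposited values were more spread out on most line arrays than on the controls. The SD of the log2 values was 0.68 to 0.70 on the control arrays, 0.87 to 0.97 on the BLJ arrays and 0.81 to 1.0 on the JKD arrays. On the SCR arrays it was 0.90, 0.67 and 0.90. Of the 9 probe sets for the hybridization controls bioB, bioC, bioD and cre, RNAs added to the samples that do not come from the plant, 8, 7 and 7 were lower in the BLJ, JKD and SCR lines after normalization. The 2 cre probe sets had a log2 fold change of 0.00 in the JKD and SCR lines. Their means there equalled those of the controls (56.0 and 46.4), because quantile normalization gives equal values to equal ranks. The 0.00 therefore does not show that they were unchanged. The median log2 fold change of the 9 was −0.19 in the BLJ line, −0.22 in the JKD line and −0.16 in the SCR line, and 4, 4 and 0 of them were called lower. On the deposited values 8, 9 and 9 of them were lower, the medians were −0.15, −0.19 and −0.20, and 2 were called lower in each line. The labels name 2 labelling protocols, and which array had which is not known here. Heat shock genes separated the arrays in another way. Their mean log2 value over 10 measured genes, a list put together after the values were seen, was 1.45 on control 3, 1.32 on BLJ 1 and 1.58 on BLJ 3. It was 0.86 and 0.98 on control 1 and control 2, and at most 1.11 on the BLJ 2, JKD and SCR arrays. The first principal component held 35.9% of the variance and placed the same 3 arrays highest.

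**Figure D1:**
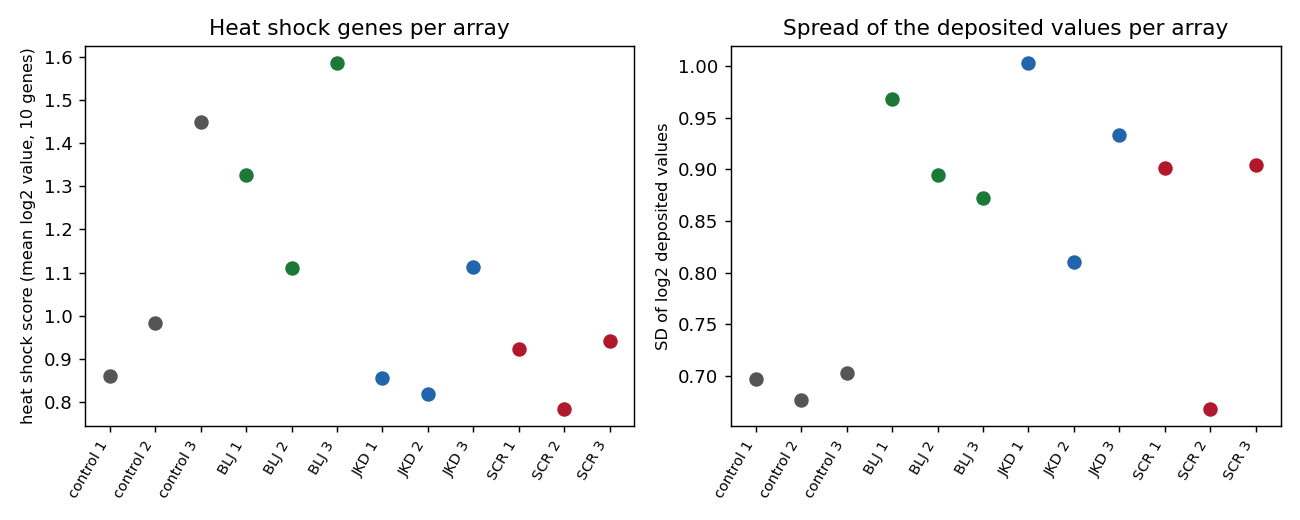
Heat shock score (left, mean log2 quantile-normalized value of 10 genes) and SD of the log2 deposited values (right) on each of the 12 arrays, coloured by group. Control 3, BLJ 1 and BLJ 3 have the highest heat shock scores (1.45, 1.32 and 1.58), and the control arrays with SCR 2 have the lowest spread (0.67 to 0.70).

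The probe sets of BLJ and JKD were not raised on the arrays labelled for them. BLJ (AT1G14580) averaged 0.804 ± 0.0210 (SD, n = 3) in the BLJ line, 0.923 ± 0.0198 in the controls, 0.942 ± 0.0150 in the JKD line and 0.980 ± 0.0501 in the SCR line. JKD (AT5G03150) averaged 0.838 ± 0.00716 in the JKD line, 0.859 ± 0.0353 in the controls, 0.780 ± 0.0240 in the BLJ line and 0.933 ± 0.0368 in the SCR line. BLJ fell in the BLJ line (log2 fold change −0.11 ± 0.03 SE, adjusted p = 0.0334), a call that was lost without control 1, BLJ 1, BLJ 2 or BLJ 3. Where these probe sets lie relative to the UAS constructs is not known here, so they check neither the constructs nor the labels. The SCR probe set is unnamed here. The lines are therefore called BLJ, JKD and SCR by their labels alone.

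In the BLJ line, several class III peroxidases, secreted enzymes that act on the cell wall, were among the genes that changed most, in both directions. Prx37 (AT4G08770) averaged 1.91 ± 0.204 in the BLJ line against 4.33 ± 0.357 in the controls (n = 3 each), a log2 fold change of −0.95 ± 0.10. AT4G11290 averaged 5.26 ± 1.60 against 10.3 ± 0.609, while AT4G30170 rose from 15.9 ± 1.42 to 27.1 ± 4.31 (−0.92 and 0.73). The size depended on the scaling: on the deposited values and after median centring, Prx37 had −0.51 and −0.46, AT4G11290 −0.39 and −0.34, and AT4G30170 1.29 and 1.34. F6'H1 (AT3G13610), an enzyme of scopoletin synthesis induced by iron deficiency, rose from 1.57 ± 0.389 to 4.02 ± 0.934 (log2 fold change 1.05 ± 0.18, adjusted p = 0.0083). PYE, the other member of the iron deficiency list that was tested, was not called (0.01, adjusted p = 0.916). In all, 678 probe sets changed in limma's test, 290 higher and 388 lower, with a median absolute log2 fold change of 0.16. An unadjusted p under 0.05 was reached by 3044.

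The peroxidase family was chosen for a test after these values were seen. Of 37 members tested, 2 rose and 6 fell in the BLJ line (Fisher's exact test against other genes, one-sided, p = 0.000104), a count that includes the members that led to the choice. Without the leading genes named for their fold change, 4 of 33 members fell and 0 rose (exact p = 0.0386). Without BLJ 3 the family had 3 calls, all lower, and without the leading genes 1 (exact p = 0.298). The family did not pass camera as a set that moves one way (adjusted p = 0.0587 with the preset and 0.621 with an estimated correlation). AT2G39040 (−0.47), AT4G16270 (−0.36), AT4G36430 (−0.40) and AT5G24070 (−0.27) were the other members that fell. In the JKD line 1 member rose (AT4G33870, 0.09) and 1 fell (AT2G39040, −0.40), with p = 0.262 by the same exact test, and in the SCR line 3 fell (exact p = 0.000261), all of them leading genes, so that 0 of 34 members changed without these. The SCR count was 0 without BLJ 1, BLJ 3, JKD 1, SCR 1 or SCR 2, and the JKD count was 0 without JKD 1 or JKD 3. Whether the lines differ in the number of changed members was not tested.

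**Figure D2:**
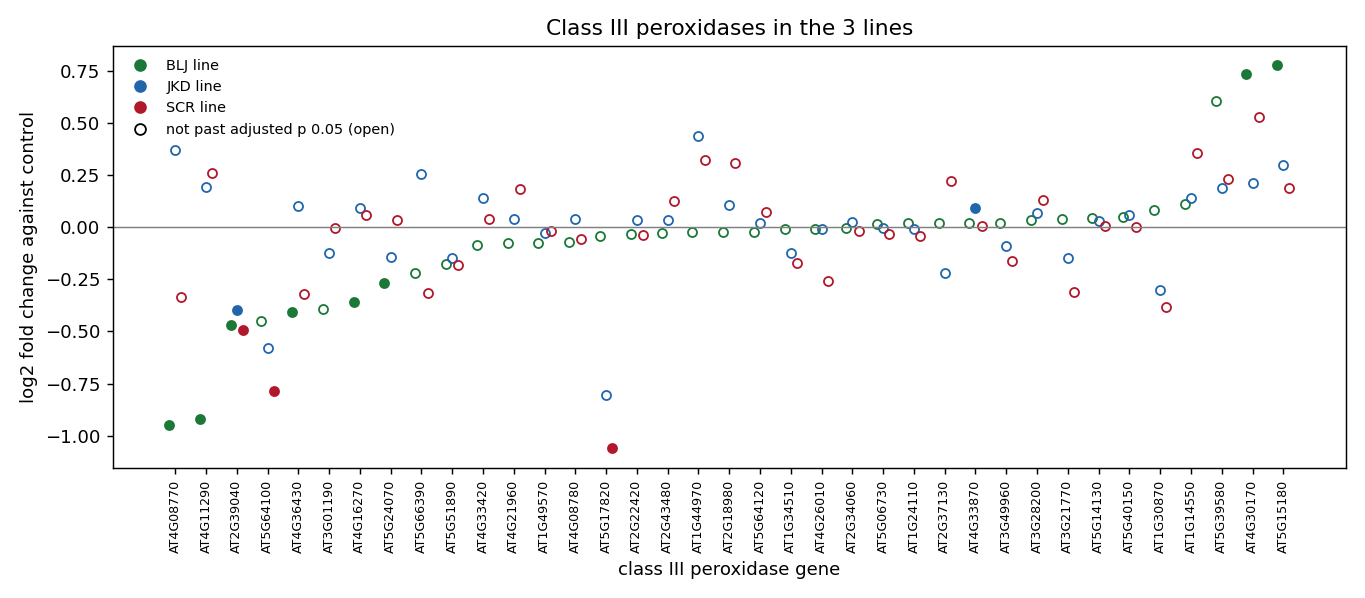
Log2 fold change against the control of the 37 class III peroxidase genes tested, in the BLJ, JKD and SCR lines, ordered by the value in the BLJ line. Filled points passed adjusted p under 0.05; 2 rose and 6 fell in the BLJ line, and AT2G39040 fell in all 3 lines.

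Among the other leading genes that rose in the BLJ line, the log2 fold changes were 0.95 for AT2G16005, 0.82 for AT4G22610, 0.78 for AT5G41810 and 0.78 for the peroxidase AT5G15180. They were 0.64 for AT4G23670, 0.57 for AT1G60010, 0.53 for AT1G67350 and 0.49 for AT1G56700. Among the leading genes that fell were the defensin-like genes LCR68 (−0.85) and PDF2.5 (−0.67), the plastid fatty acid synthesis gene accD (−0.77) and MSRB5, a methionine sulfoxide reductase (−0.71). AT2G43590 (−0.77), AT2G14900 (−0.72), AT1G62480 (−0.70) and ccb382, a mitochondrial cytochrome c maturation gene (−0.66), fell as well. Falls were smaller on the other scales, with −0.31 for LCR68, −0.23 for accD, −0.28 for MSRB5 and −0.05 for ccb382 after median centring, where AT5G41810 rose by 1.23. Over all probe sets tested, groups without overlap made up 21.0%, where chance gives 10%.

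The SHR, SCR and BIRD network list holds regulators of ground tissue identity with some of their targets, and 6 of its 17 members were measured. Of these 6, 2 fell in the BLJ line over all genes tested, BLJ itself and the target TRI (−0.20 ± 0.04, adjusted p = 0.016). Adjusted over the list alone, 3 fell. BLJ and TRI were not called over all genes without control 1 or BLJ 3. As a set lower in the BLJ line, the list passed the competitive test camera with a preset correlation (adjusted p = 0.0383). It did not pass with an estimated correlation (adjusted p = 0.223). The call was also lost without a filter, with intensities under 1 set to 1 and with the replicate number as a fixed block. It was lost without control 1, control 2, BLJ 2, BLJ 3, JKD 3, SCR 1 or SCR 3, where 0 lists passed. JKD (−0.08), AT3G45260 (−0.03), AT5G41920 (0.00) and SLY2 (0.01) did not pass. Of 4 measured cortex genes, 2 rose over all genes and adjusted over the list alone: AT1G09750 (0.47 ± 0.10) and the nitrate transporter gene AT3G21670 (0.13 ± 0.03). Both calls were lost without BLJ 1, and that of AT3G21670 also without control 1, control 2 or BLJ 3. The other cortex genes measured, AT1G62500 (−0.02) and AT1G62510 (0.04), did not pass. The cortex list as a whole did not pass camera (adjusted p = 0.125 with the preset correlation).

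Single members of other fixed lists also changed in the BLJ line. The phloem gene OPS fell (−0.12), as did WES1, an auxin-conjugating enzyme (−0.21), and UGT78D2, a flavonol glucosyltransferase (−0.56). RCA, the Rubisco activase gene, rose (0.21). The calls of OPS, WES1 and RCA were lost without BLJ 1 or BLJ 3. No call was made for the best-ranked members of the endodermis (AT1G61590 −0.34, GSO1 −0.17), root hair (EXPA18 −0.02, EXPA7 −0.02), xylem (PHV −0.01, LHW 0.01) and lateral root lists (LBD29 −0.06, LBD16 −0.07). The same held for BBM of the stem cell niche (−0.07), AT4G04460 of the root cap (−0.15), PRL of DNA replication (0.05), AUR2 (−0.02) and AUR3 (0.01) of mitosis, GID1C (−0.04) and GID1A (0.02) of gibberellin perception, and STZ (−0.52) and WRKY53 (−0.09) of the wound response. In the mitosis and gibberellin lists, 0 of 3 members passed in the BLJ line, also when adjusted over the list alone, and for auxin response 1 of 3 fell by either count. The median of the auxin list was −0.05 in the BLJ line and its mean 0.003.

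The BLJ count depended on single arrays: 352 probe sets passed without control 1, 256 without BLJ 1 and 186 without BLJ 3. It was 38 without control 3, BLJ 1 and BLJ 3, the arrays high in heat shock genes, a fit with BLJ 2 as the only BLJ array, which was assumed to vary like the other groups and cannot check the heat shock arrays. It was 34 with the 6 BLJ and control arrays alone. With each array centred on its median the direction turned, to 1993 higher and 535 lower, and the deposited scale gave 1533 and 1406. Of 53 named calls in the BLJ line, 18 held whichever of the 6 BLJ and control arrays was left out, F6'H1, AT5G41810, AT4G23670, Prx37, AT4G11290, MSRB5, ccb382 and UGT78D2 among them. The call of AT4G30170 was lost without BLJ 3. Simulated changes of 0.25 on the log2 scale were recovered for 62.7% of probe sets in this comparison, and of 0.5 for 88.1%. That simulation had noise independent between probe sets, so it does not cover the dependence on single arrays.

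**Figure D3:**
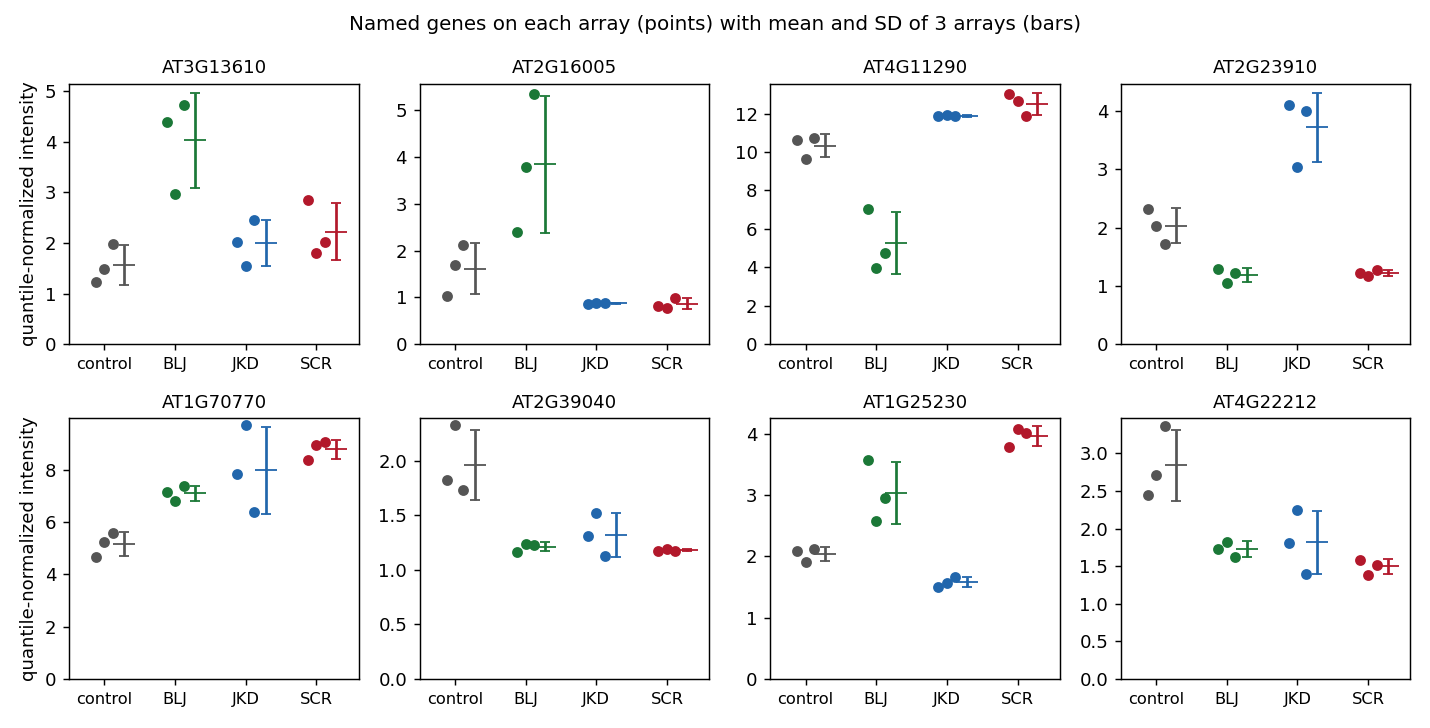
Quantile-normalized intensity (linear axis from 0) of 8 named genes on each array, with points for arrays and bars for the mean and SD of the 3 arrays of a group. AT3G13610 and AT2G16005 are highest on BLJ arrays, AT4G11290 is lowest there, AT2G23910 is highest on JKD arrays, and AT2G39040 is lower in all 3 lines than in the controls.

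In the JKD line, AT2G23910 rose most among the named genes, from 2.03 ± 0.30 in the controls to 3.72 ± 0.587 (n = 3 each), a log2 fold change of 0.69 ± 0.10 with an adjusted p of 0.00885. MDH, the plastid malate dehydrogenase gene, rose from 1.98 ± 0.249 to 2.90 ± 0.155, and OTC, of arginine synthesis, from 1.49 ± 0.191 to 2.08 ± 0.138. AT5G19110 fell from 11.2 ± 2.65 to 6.56 ± 0.873 and AT2G30930 from 4.24 ± 0.875 to 2.39 ± 0.0990. In all, 437 probe sets changed in limma's test, 138 higher and 299 lower, with a median absolute log2 fold change of 0.15, and 3038 had an unadjusted p under 0.05.

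Other genes that rose in the JKD line were AT1G70770 (0.55), AT2G46540 (0.39), AT1G74470, a geranylgeranyl reductase gene of chlorophyll synthesis (0.38), AT3G17130 (0.38), AT5G57785 (0.35), AT1G54540 (0.29) and AT4G29260 (0.27). Those that fell included ccb382 (−0.64), AT5G26260 (−0.61), AT3G19240 (−0.57, but 0.05 when arrays were centred on their medians), AT3G12510 (−0.51) and AT4G22212 (−0.50). AT1G20823 (−0.44), AT3G28320 (−0.42) and AT1G20070 (−0.42) fell too. After median centring AT2G23910 had 1.09, AT1G70770 1.14, AT5G19110 −0.09, AT2G30930 −0.17, AT5G26260 −0.03 and ccb382 −0.02. WES1 fell (−0.26 ± 0.05), and it was the single member of a fixed list that passed; 1 of the 3 auxin response genes fell by either count, over all genes or adjusted over the list alone.

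Of the network genes in the JKD line, 0 of 6 passed over all genes and adjusted over the list alone, with values from −0.03 (AT3G45260) to 0.02 (AT5G41920). The cortex genes AT1G09750 (0.26) and AT1G62510 (0.05) did not pass, and 0 of 4 cortex, 0 of 3 mitosis and 0 of 3 gibberellin genes passed by either count. Further values below the threshold were GSO1 0.24, EXPA7 −0.15, EXPA18 −0.11, LHW 0.06, OPS −0.10, LBD29 −0.06, LBD16 −0.15, BBM −0.08, PRL 0.07, STZ −0.28, UGT78D2 0.29, RCA 0.15, F6'H1 (AT3G13610) 0.25 and PYE 0.03. None of the 5 fixed lists passed camera in this line.

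The JKD count fell to 7 without JKD 1, 12 without JKD 3, 219 without JKD 2, 229 without control 1, 275 without SCR 1 and 276 without SCR 3, and rose to 680 without control 2. It was 183 without the 3 arrays high in heat shock genes, where 125 of the 437 calls were kept, 13 with the 6 JKD and control arrays alone, and 2 with intensities under 1 set to 1. The direction depended on the scaling: median centring gave 3120 higher and 727 lower, and the deposited scale 2092 and 1925. Of 37 named calls, 0 held whichever array was left out: each was lost without JKD 1 or JKD 3. Simulated changes of 0.25 were recovered for 70.1% of probe sets and changes of 0.5 for 86.6%, again with independent noise that leaves out the dependence on single arrays.

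In the SCR line, EXO, a cell expansion gene of brassinosteroid responses, rose from 1.33 ± 0.139 to 3.89 ± 1.31 (n = 3 each), a log2 fold change of 1.13 ± 0.18 with an adjusted p of 0.0318. AT1G25230 rose from 2.04 ± 0.119 to 3.97 ± 0.157 and AT1G70770 from 5.16 ± 0.454 to 8.78 ± 0.361. The peroxidases AT5G17820 and AT5G64100 fell, from 5.77 ± 2.37 to 2.29 ± 0.427 and from 5.09 ± 1.09 to 2.67 ± 0.731. Both calls were lost without control 3, SCR 1 or SCR 2. In the JKD line these 2 genes had −0.81 and −0.58, short of the threshold in limma's test (adjusted p = 0.0548 and 0.0611). In all, 63 probe sets changed in limma's test, 27 higher and 36 lower, with a median absolute log2 fold change of 0.28, and 2645 had an unadjusted p under 0.05.

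AT2G02780 (0.51), AT3G27390 (0.50), AT1G30440 (0.42), AT1G67480 (0.29), AT3G24450 (0.27) and AT5G58530 (0.25) also rose in the SCR line. The other genes that fell were AT3G24670 (−0.80), AT2G34910 (−0.75), AT2G45750 (−0.72), AT4G22212 (−0.68), AT4G02940 (−0.58), the peroxidase AT2G39040 (−0.50), AT3G18280 (−0.43) and WES1 (−0.30). After median centring EXO had 1.19, AT5G17820 −0.67, AT5G64100 −0.40, AT3G24670 −0.44 and AT4G02940 −0.22. WES1 was the single fixed-list member that passed over all genes; adjusted over the list alone, 1 auxin response gene rose and 1 fell, with a list median of 0.01, a mean of 0.11 and a test direction that was lower. Of the network genes, 0 of 6 passed by either count, with JKD at 0.07 and BLJ (AT1G14580) at 0.05. The same was true of 0 of 4 cortex genes (AT1G62500 0.04, AT1G09750 0.15), 0 of 3 mitosis and 0 of 3 gibberellin genes.

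Values that did not pass in the SCR line were AT1G61590 −0.25, GSO1 −0.09, EXPA7 −0.20, EXPA18 −0.15, LHW 0.19, PHV −0.02, OPS −0.04, LBD16 −0.28, LBD29 −0.06, AT4G04460 −0.21, AUR3 0.04, PRL 0.10, WRKY53 −0.03, UGT78D2 −0.48, RCA 0.12 and AT3G13610 0.36. None of the 5 fixed lists passed camera in this line.

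The SCR count rested on single arrays of every group. It was 2 without SCR 1, SCR 2 or JKD 1, 3 without BLJ 1, 4 without BLJ 3, 18 without JKD 2, 29 without JKD 3, 38 without control 3, 101 without control 1, 141 without SCR 3 and 276 without control 2. With the 6 SCR and control arrays alone, limma called 0 probe sets, and 1991 had an unadjusted p under 0.05. Without the 3 arrays high in heat shock genes it called 6, of which AT1G25230 was the single named one. With the RNA quality covariate it called 2, and with the heat shock covariate 33. Median centring turned the split, to 31 higher and 20 lower. Of 24 named calls, 0 held whichever array was left out, and each was lost without SCR 2. Simulated changes of 0.5 were recovered for 91.0% of probe sets, with independent noise that leaves out this dependence on single arrays.

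**Figure D4:**
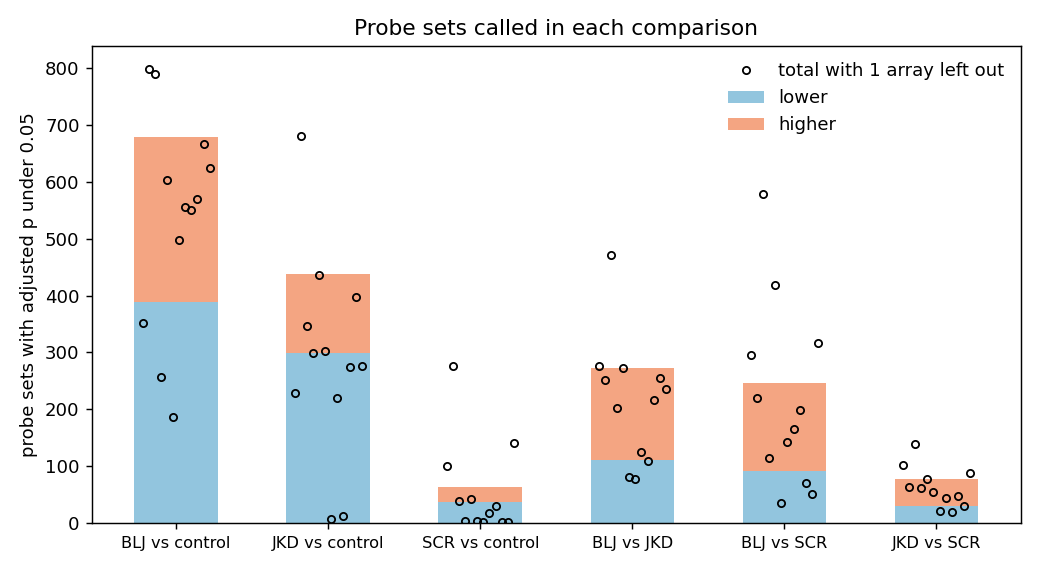
Number of probe sets with adjusted p under 0.05 in each comparison (bars from 0, lower and higher stacked) and the total when each of the 12 arrays was left out in turn (open points). The JKD total falls from 437 to 7 without JKD 1, and the SCR total ranges from 2 to 276.

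The 3 lines shared part of their changes against the control arrays, after quantile normalization mostly among probe sets that were lower. BLJ and JKD shared 35 higher and 209 lower probe sets, where independent lists give 2.51 and 7.29 and unchanged simulated groups against the same controls gave 0. BLJ and SCR shared 11 higher and 24 lower, against 0.492 and 0.877 for independent lists, and JKD and SCR shared 5 and 22, against 0.234 and 0.676. Independent lists leave out the common controls, and the simulated groups carry no change. Neither therefore shows how many shared calls the common control arrays can give. The peroxidase AT2G39040 fell in each line (−0.47, −0.40 and −0.50 in BLJ, JKD and SCR), as did AT4G22212 (−0.54, −0.50 and −0.68) and WES1 (−0.21, −0.26 and −0.30). These falls were smaller on other scales: after median centring AT2G39040 had −0.21, −0.12 and −0.28, AT4G22212 −0.15, −0.11 and −0.38 and WES1 −0.02, −0.07 and −0.15. AT2G31420, AT5G15690, AT2G40480, AT5G56460 and AT1G06690 fell by less in each, from −0.19 to −0.08, and AT5G58530 rose (0.27, 0.24 and 0.25). Altogether 20 probe sets passed in the 3 lines with a common direction, 3 higher and 17 lower, and 9 of them have 1 gene. Median centring gave BLJ and JKD 831 shared higher and 429 shared lower probe sets, and the deposited scale 562 and 1063. Of the 209 lower ones, 207 were below 0 in both lines after median centring and 172 were called lower in both.

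The 209 probe sets lower in both the BLJ and JKD lines had median log2 fold changes of −0.15, −0.16 and −0.10 in the BLJ, JKD and SCR lines, where the hybridization controls had medians of −0.19, −0.22 and −0.16. The 9 control probe sets behind these medians differed widely. They ran from −0.79 to 0.00 in the BLJ line, −0.82 to 0.00 in the JKD line and −0.71 to 0.00 in the SCR line. The same 3 control arrays stand behind each line, so part of the excess of shared calls may come from them, and 3 arrays are too few to split between the comparisons. The correlation of fold changes across probe sets was 0.337 for BLJ and JKD, 0.281 for BLJ and SCR and 0.570 for JKD and SCR, where simulated unchanged groups gave 0.502, 0.499 and 0.50. The covariances were 0.00378, 0.00341 and 0.00662, against simulated values of 0.00287, 0.00285 and 0.00285. The shared count for BLJ and JKD, 244 in all, was 4 without JKD 1, 8 without JKD 3, 84 without BLJ 3, 92 without BLJ 1, 124 without control 1, 140 without JKD 2 and 432 without control 2. For BLJ and SCR, 35 in all, it was 0 without SCR 2, 2 without BLJ 1, BLJ 3, JKD 1 or SCR 1, 11 without JKD 2, 17 without JKD 3 and 183 without control 2. For JKD and SCR, 27 in all, it was 0 without SCR 2, 1 without BLJ 1, BLJ 3, JKD 1 or SCR 1, 2 without JKD 3, 7 without JKD 2, 16 without BLJ 2, 17 without control 3, 41 without control 1 and 180 without control 2.

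Compared directly, the BLJ and JKD lines differed most in AT2G16005, Prx37 and AT2G23910. AT2G16005 averaged 3.84 ± 1.47 in the BLJ line and 0.874 ± 0.0166 in the JKD line (n = 3 each), and Prx37 averaged 1.91 ± 0.204 and 5.81 ± 0.337. AT2G23910 fell in the BLJ line (−0.53) and rose in the JKD line (0.69), a difference of −1.22 ± 0.10 with an adjusted p of 9.64e-05. AT5G41810 (1.08), AT2G32150 (1.04), AT4G22610 (0.96) and AT1G14960 (0.94) were higher in the BLJ line, and AT4G11290 (−1.11), UGT78D2 (−0.85) and AT2G14900 (−0.80) were lower. In all 273 probe sets differed, 162 higher and 111 lower in the BLJ line. The count was 78 without JKD 1, 81 without BLJ 3, 109 without JKD 3, 124 without JKD 2 and 471 without control 3, and 104 without the 3 arrays high in heat shock genes, where BLJ 2 alone stood for the BLJ line. With the heat shock covariate on all arrays it was 114, and 81 of the 273 calls were kept. Of 10 named calls, 6 held whichever of the 6 BLJ and JKD arrays was left out. Those of AT2G32150, AT4G22610, AT1G14960 and AT2G14900 did not.

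Between the BLJ and SCR lines, 247 probe sets differed, 155 higher and 92 lower in the BLJ line. AT2G16005 (1.49), AT5G16010 (1.24), AT4G22610 (1.15), AT5G41810 (1.14) and the peroxidase AT5G17820 (1.02) were higher in the BLJ line. AT2G43610 (−1.18), AT4G11290 (−1.18), EXO (−0.99) and the SKU5-like genes sks15 (−1.16) and sks16 (−1.04) were lower. AT4G11290 averaged 5.26 ± 1.60 in the BLJ line and 12.5 ± 0.587 in the SCR line (n = 3 each). The count was 35 without BLJ 3, 51 without SCR 2, 71 without SCR 1, 114 without BLJ 1, 142 without JKD 1, 418 without BLJ 2 and 578 without control 3. It was 52 without the 3 arrays high in heat shock genes, again with BLJ 2 alone. With the heat shock covariate on all arrays it was 14, with 13 of the 247 calls kept. With the RNA quality covariate it was 124, with 102 kept. Of 10 named calls, 3 held whichever of the 6 BLJ and SCR arrays was left out: AT2G16005, AT5G41810 and AT4G11290. Those of AT2G43610, sks15 and sks16 were lost without BLJ 1, BLJ 3, SCR 1, SCR 2 or SCR 3.

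Between the JKD and SCR lines, 78 probe sets differed, 49 higher and 29 lower in the JKD line. The flavonol glycosyltransferase genes UGT78D2 (0.77) and AT1G06000 (0.73) were higher in the JKD line, with AT2G23910 (1.19), AT5G03610 (0.77) and Prx37 (0.71). AT3G15450 (−1.71), EXO (−1.16), AT1G25230 (−1.03), AT2G30930 (−0.88) and AT4G35750 (−0.58) were lower. AT1G25230 averaged 1.58 ± 0.0814 in the JKD line and 3.97 ± 0.157 in the SCR line (n = 3 each, adjusted p = 0.000219). The count was 20 without JKD 3, 21 without JKD 1, 30 without SCR 2, 44 without JKD 2, 48 without SCR 1 and 139 without control 3. It was 141 without the 3 arrays high in heat shock genes, and 75 of the 78 calls were kept there. With the heat shock covariate it was 170, with 77 of the 78 kept. Of 10 named calls, 4 held whichever of the 6 JKD and SCR arrays was left out: AT2G23910, AT5G03610, UGT78D2 and AT1G25230. The call of AT1G06000 was lost without any 1 of these arrays.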

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

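The tests of the BLJ line and of RNA degradation for the heat shock genes, both tests of the BLJ and JKD probe sets, the test of the hybridization controls and the simulations of an unchanged SCR line were chosen after the results were seen.

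Heat shock genes were high on control 3, BLJ 1 and BLJ 3, and the split of the 6 control and BLJ arrays that set these 3 against the other 3 called 832 probe sets, more than the 678 of the real groups, which points to a structure of the samples. A difference in array scale is argued against, since control 3 lay at least 0.43 above the mean of the other controls on the quantile-normalized, the deposited and the median-centred values. By its label control 3 carries no driven BLJ. An effect of the BLJ line stays open for BLJ 1 and BLJ 3, since the 3 BLJ arrays against the 3 controls gave an exact permutation p of 0.3 (two-sided, BLJ mean 0.24 above the controls), where 3 arrays against 3 allow 0.1 at the lowest. RNA degradation stays open as well, since 0 of the 3 arrays had a log2 3'/5' ratio at or below the median array. The highest log2 ratios were however those of BLJ 2 (1.47) and JKD 1 (1.22). Control 3, BLJ 1 and BLJ 3 had 1.20, 1.08 and 1.07.

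The 209 probe sets lower in both the BLJ and the JKD lines had medians of −0.15 and −0.16. Control arrays that stand apart from all lines stay open: the median in the SCR line was 0.654 of the mean of the other lines' medians. The rule written in advance took a ratio this high as what this explanation predicts. An SCR line at the control means was simulated 50 times in each of 2 ways. With all lines unchanged the ratio was 0.621 on average, where the lines share the noise of the control arrays. With the BLJ and JKD lines at their fitted effects it was 0.0914, but 482 probe sets on average were called lower in both, against 209. The simulations therefore do not decide this question. A technical difference between control and line arrays may contribute. The hybridization controls, which carry no plant RNA, had medians of −0.19 and −0.22 in the BLJ and JKD lines. All 9 line arrays (−0.40 to −0.12) lay below the controls (−0.02 to 0.01) on the normalized values, with BLJ 2 (0.18) and JKD 1 as exceptions on the deposited values. The source of such a difference was not tested. The labelling protocol is not given per array, and these controls do not show whether it has a part. The spread of the arrays stays open, since SCR 2, which has the spread of the controls, gave −0.086, nearer to the other SCR arrays (−0.11 each) than a cause in spread would need but not as far from 0. A biological effect common to the lines stays open and was not tested, and the hybridization controls do not show which of the 209 probe sets a technical difference would reach.

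The BLJ and JKD probe sets were not raised on the arrays labelled for these factors. Signal near the floor stays open, because neither probe set was above the percentile 67.9 of an array. A swap of labels between groups is not supported by any array, the highest being 1.09 times the highest control array, but this cannot exclude a swap if the probe sets do not detect the constructs. Weak expression from the constructs stays open and was not tested.

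With 10 splits of 6 arrays, the splits are too few for a share under 0.05 in every comparison. For BLJ against the control, 2 of the 10 splits called 678 or more. For JKD (437) and SCR (63) against the control, and for BLJ against JKD (273), BLJ against SCR (247) and JKD against SCR (78), 1 of the 10 did, and the highest other split called 0.

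The lines differed from one another when tested directly, in 273 probe sets for BLJ and JKD, 247 for BLJ and SCR and 78 for JKD and SCR. AT2G23910, which passed in opposite directions against the control in the BLJ and JKD lines, differed by −1.22 between them.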

How the results depend on the processing

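Plain log2 without an offset, the fit without control 3, BLJ 1 and BLJ 3 and the heat shock covariate were chosen after the data were seen. Counts are given for BLJ, JKD and SCR against the control (678, 437 and 63 as reported), then for BLJ against JKD, BLJ against SCR and JKD against SCR (273, 247 and 78). All 6 counts stayed within 1.5 times of these with the offset at the 40th percentile, without a filter, with a random replicate block and on plain log2, where all 144 results called for named genes also kept their direction and call. How far a signal lies above background is not known on this scale; 66.1% of the values were under 1 and the lowest was 0.513, so changes of dim genes had little room to show. Where no reason is given below, the cause was not tested.

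With values under 1 set to 1 and no offset the counts were 47, 2, 2, 97, 44 and 41. Of the calls as reported, 43, 1, 1, 81, 34 and 28 were kept. That floor gives most values a common level, and it put 271, 188, 18, 37, 40 and 8 of these calls at a fold change of 0. Other calls were lost without being at 0, and the cause of their loss was not tested. Leaving out the dimmest 50% gave 365, 146 and 31 for the lines against the control. On the deposited scale BLJ gave 2939 (1533 higher, 1406 lower, against 290 and 388 as reported), JKD 4017 (2092 and 1925, against 138 and 299) and JKD against SCR 119; fold changes there followed the mean level of the probe sets (Spearman's rho across probe sets 0.850 for BLJ and 0.867 for JKD, against 0.016 and 0.052 after quantile normalization), with the wider spread of the line arrays. Median centring gave 2528 for BLJ (1993 higher, 535 lower) and 3847 for JKD (3120 and 727), and shifted the split for SCR (31 and 20, against 27 and 36), BLJ against SCR (278 and 74, against 155 and 92) and JKD against SCR (89 and 20, against 49 and 29). Moderation without trend and robust options gave 372, 150 and 5 for the lines against the control and 144 for BLJ against SCR. Array weights gave 1378, 1224 and 334 between the lines. With the RNA quality covariate SCR had 2 and BLJ against SCR 124.

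Without control 3, BLJ 1 and BLJ 3 the counts were 38, 183, 6, 104, 52 and 141, with 32, 125, 5, 74, 31 and 75 of the calls kept; fewer arrays were fitted. The counts with BLJ (38, 104 and 52) rest on 1 BLJ array, BLJ 2, assumed to vary like the other groups, so they do not show whether the BLJ calls hold without the heat shock arrays. The heat shock covariate gave SCR 33, BLJ against JKD 114, BLJ against SCR 14 and JKD against SCR 170. Fitting only the 6 arrays compared gave 34, 13 and 0 against the control (for SCR 1991 had an unadjusted p under 0.05 in limma) and 120 for JKD against SCR. At least 1.5-fold was reached by 41, 12, 13, 60, 52 and 19, and an adjusted p under 0.01 by 121, 26, 0 (2645 at an unadjusted p under 0.05), 68, 44 and 28, as stricter thresholds must lower counts.

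The replicate numbers name the arrays only: the residuals of 18 same-numbered pairs correlated at −0.19 to 0.62, 12 of them over 0.1, and 7 of 12 arrays correlated best with their own number, a hint from the data and not the design. With the replicate block SCR had 205, BLJ against JKD 529, BLJ against SCR 639 and JKD against SCR 143, the overlap of BLJ and SCR was 72 and that of JKD and SCR 72, and 0 fixed lists passed. It kept the call of 140 of the 144 results of named genes and moved no other count past 1.5 times.

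A list counts here once for each line in which it passed. Of the 15 tests of fixed gene lists, 1 passed as reported. With an estimated correlation 0 did. With fry 6 of the 15 tests passed, and fry asks whether a list moves and not whether it moves more than other genes. None (0) passed without a filter, with values under 1 set to 1 or without control 3, BLJ 1 and BLJ 3. Of the 60 tests of added lists 12 passed, 0 with an estimated correlation and 2 with fry. The shared calls of BLJ and JKD, BLJ and SCR, and JKD and SCR (244, 35 and 27) were 1, 1 and 1 with values under 1 set to 1, and 5, 4 and 3 without control 3, BLJ 1 and BLJ 3, again with 1 BLJ array. On the deposited scale they were 1625 for BLJ and JKD and 41 for JKD and SCR. The correlations of fold changes (0.337, 0.281 and 0.570) were 0.799, 0.673 and 0.792 on the deposited scale, and 0.472 for JKD and SCR without control 3, BLJ 1 and BLJ 3.

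When each array was left out in turn, the counts ranged from 186 to 799, 7 to 680, 2 to 276, 78 to 471, 35 to 578 and 20 to 139. The tests of lists that passed ranged from 0 to 1 (fixed) and 9 to 16 (added). The shared calls ranged from 4 to 432, 0 to 183 and 0 to 180, and the correlations from 0.243 to 0.458, 0.147 to 0.421 and 0.473 to 0.692. A fit that left out an array of a group assumed that its other 2 vary like the other groups. Of 864 results of named genes with an array left out, 470 kept the call, 394 lost it and 0 changed sign. Of the 144 results of named genes, 89 kept the call on the deposited scale, 82 after median centring, 20 with values under 1 set to 1 and 44 without control 3, BLJ 1 and BLJ 3. Directions turned for AT3G19240 in the JKD line (0.045 after median centring), GSTU25 in the BLJ line (0.16 on the deposited scale and 0.21 after median centring) and GSTU27 in the BLJ line (0.028 after median centring).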

Other observations

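The array means of the gene lists were computed after the results of the lists had been seen.

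Genes of cytosolic ribosomal proteins separated the arrays high in heat shock genes from the rest. The mean log2 value of 108 measured genes was 2.07 on control 3, 2.33 on BLJ 1 and 2.25 on BLJ 3, and 2.52 to 2.79 on the other 9 arrays. Against the controls the list was higher in the JKD line (median 0.16) and the SCR line (0.15), with adjusted p = 8.23e-05 in both at the preset and 0.968 with an estimated correlation, and 0 members passed in either line. The JKD and SCR arrays lay between 2.52 and 2.63, around control 1 (2.61) and control 2 (2.55), so the difference rests on control 3. In the BLJ line the median was 0.03, and 1 member rose (AT3G28500, 0.15), a call lost without BLJ 3. Control 3 was also the highest array for 6 measured root hair genes, among them EXPA7 and EXPA18 of the fixed list. Their mean was 1.02 on control 3, 0.68 and 0.61 on the other controls, 0.75 to 0.79 on the BLJ arrays, 0.61 to 0.66 on the JKD arrays and 0.51 to 0.57 on the SCR arrays. The list was lower in the JKD line (median −0.13, adjusted p = 0.0193 at the preset and 0.864 with an estimated correlation) and in the SCR line (median −0.21, 8.23e-05 and 0.702). Over all genes 0 members passed in either line, and adjusted over the list alone 2 fell in the JKD line and 5 in the SCR line. For 4 root cap genes the SCR median was −0.21 (adjusted p = 0.0158 at the preset and 0.768 with an estimated correlation), and control 3 was again the highest array (1.1). SCR 3 (0.769) lay above control 1 (0.757).

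Genes of the plastid genome were lower as a set in each line, with medians over 69 genes of −0.09, −0.08 and −0.12 in the BLJ, JKD and SCR lines. The adjusted p values were 4.6e-06, 0.000228 and 1.07e-11 at the preset, and 0.873, 0.873 and 0.768 with an estimated correlation. Each line overlapped the controls: the mean log2 value of the list was 1.33 on control 1, the lowest control. It was higher on BLJ 2 (1.44), JKD 2 (1.39) and SCR 2 (1.37). The other line arrays (1.13 to 1.25) lay below every control. Replicate 2 was the highest array in every group, the controls included. On the deposited values the medians were 0.03, 0.06 and −0.06, so the direction turns in the BLJ and JKD lines. In the BLJ line 5 members fell, among them rbcL (−0.29) and petN (−0.32), and 4 fell in the JKD line and 0 in the SCR line. The BLJ count was 1 without BLJ 1 or BLJ 3, and the JKD count 0 without JKD 1 or JKD 3. Nuclear photosynthesis genes were higher in the SCR line (median 0.07 over 10 genes, adjusted p = 0.00192 at the preset and 0.702 with an estimated correlation), with 0 members past the threshold. Their mean log2 value on SCR 3 (0.618) lay below that on control 1 (0.622). In the BLJ line, tau glutathione transferases and UGT73 glycosyltransferases, enzymes of detoxification, were lower (median −0.05 over 14 genes, adjusted p = 0.0204 at the preset and 0.702 with an estimated correlation). The members that fell were GSTU25 (−0.40), GSTU27 (−0.53) and UGT73B1 (−0.26), but GSTU25 was at 0.16 on the deposited values and both GSTU genes were above 0 after median centring, and the calls of GSTU25 and UGT73B1 were lost without control 1, BLJ 1 or BLJ 3. Of 38 UDP-glycosyltransferases 1 rose and 5 fell (median −0.03, adjusted p = 0.0161 at the preset and 0.768 with an estimated correlation), and 1 of these 6 was called without control 1, BLJ 1 or BLJ 3. Of 9 endodermal barrier genes AT4G11290 and AT2G48130 (−0.47) fell in the BLJ line (median −0.22, adjusted p = 0.0193 at the preset and 0.864 with an estimated correlation), while the median of the list was 0.24 on the deposited values and the call of AT2G48130 was lost without control 1, control 3, BLJ 2 or BLJ 3. The wall enzyme gene XTH32 rose in the BLJ (0.31) and JKD (0.16) lines, and the expansin gene EXPA8 fell in the JKD line (−0.26); both JKD calls were lost without JKD 1 or JKD 3.

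Array weights, which limma sets from the residuals, ran from 0.332 on control 3 to 2.65 on JKD 1.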
